A study of Mus musculus with 10 samples.

How the data were processed

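PolyA RNA was measured in 10 libraries of GFP-sorted mouse bone marrow cells that carried an empty vector, full-length ASXL2 or 1 of 3 mutant forms of ASXL2, with 2 libraries in each group. The deposited tables give, per library, an estimated count and a TPM value (a length-scaled share of transcripts) for each of 115088 transcripts. Per the submitters' processing notes the tools were kallisto and DESeq2 and the genome build was mm10, with no version or role given. The estimated counts and the TPM values carry the column names that kallisto writes, per the file headers. Read trimming, the transcript index and any filter are not given in the sources used here. Kallisto shares a read among the transcripts it fits, so genes with near-identical copies have uncertain counts, and no strand setting is stated, so overlapping antisense genes cannot be told apart.

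Transcripts were summed per gene through the GENCODE M21 annotation of GRCm38 (mm10). Of the transcripts, 114200 (99.2%) matched and 888 did not, and the matched ones carried between 99.3 and 99.6% of the counts of each library. This gave 47311 genes, of which 78 symbols belong to more than 1 gene identifier and were kept apart by identifier. Unmatched transcripts were left out, and no mitochondrially encoded gene was among the matched ones. The deposited estimated counts were rounded to whole numbers after summing. The totals lay between 52422686 and 79320702 per library, and between 15624 and 17240 of the genes had at least 10 counts in a library. For the remaining genes counting error is large.

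Groups and replicate numbers were taken from the labels. The deposited data of 4 mutant libraries carry another mutant number in their names than their label, and 2 of them also another batch. The mutants were therefore pooled in the main comparisons, and single mutants are reported by label only. The comparisons, tests, alternatives, named gene rule and gene lists were chosen before the data were examined, except where the text says otherwise. The genes picked in the simulations of unchanged groups, by the named gene rule and in lists as long as the real ones, and the simulations with each library left out were added after the values were seen.

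Genes were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test, with TMM scaling and edgeR's default expression filter (10 counts, smallest class of 2), which kept 17810 genes. All 10 libraries entered 1 fit with 3 classes, and single mutants were tested in a fit with 5 groups. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. CPM values are TMM-scaled unless stated, and log2 CPM for principal components and library correlations used a prior count of 2. The 29 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested. An estimated correlation and fry were run beside it, on the fit without a block only. The difference between the batches therefore enters both. List medians per library and within batches were taken on log2(CPM + 0.1). DESeq2 1.42.0 was run as an alternative, as was limma on log2(TPM + 1), where the pseudocount of 1 understates the change of low genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

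The named genes are those past the threshold with at least 5 CPM in the higher class, without predicted gene symbols, the 10 with the largest rise and the 10 with the largest fall. Missing places were filled from the fit with the replicate block. Added to these were up to 4 members of each list with the smallest p, the Asxl genes and Bap1, and for each single mutant the 5 genes with the smallest p.

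The labels give the replicate number as a batch, and this is where the pairing comes from. Deviations from the group means correlated at 0.491 between the empty vector and mutant 2, at 0.525 between the empty vector and full-length ASXL2 and at 0.578 between mutant 2 and full-length ASXL2. The other 7 pairs of groups lay between -0.145 and 0.0169. The replicate block was fitted as an alternative both by label and by the batch in the deposited names.

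The scripts were tested on simulated counts with the means and library sizes of the real data and 200 genes changed by known folds. The simulated counts held no batch, and their spread came from the fit without a block, here and in the simulations of unchanged groups. For full-length ASXL2 against the empty vector, with 17479 genes tested, 71.2% of 4-fold, 37.3% of 2-fold and 7.46% of 1.5-fold changes were recovered, with 2 false calls. For the mutants against the empty vector, with 17466 genes tested, the shares were 71.2, 35.8 and 11.9%, with 1 false call. For the mutants against full-length ASXL2, with 17447 genes tested, they were 69.7, 47.8 and 14.9%, with 4 false calls. Alternatives were DESeq2 and its size factors, no filter, a stricter filter (1 CPM in 4 libraries), a fold threshold of 1 on the log2 scale, transcript length offsets, a fit with 5 groups, only the libraries compared, only libraries whose deposited name and label match, both blocks, and each of the 10 libraries left out in turn.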

Results

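PolyA RNA was sequenced from mouse bone marrow cells that carried the stem and progenitor surface phenotype (lineage-negative, Kit-positive). The cells received an empty vector, full-length ASXL2 or 1 of 3 mutant forms of ASXL2, a chromatin scaffold protein that binds the histone H2A deubiquitinase BAP1. GFP-positive cells were sorted and expanded with IL3, IL6 and SCF, which are growth factors for early blood cells. There were 2 libraries in each of the 5 groups, 10 libraries in all, and the 3 mutant groups were also pooled into 1 class of 6. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Estimated counts per library ranged from 52422686 to 79320702, and between 15624 and 17240 genes had at least 10 counts. The lowest correlation of log2 CPM between 2 libraries was 0.975 and the highest was 0.991, and no library was a copy of another.

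The first measurement was Asxl2 itself, which checks the labels. Asxl2 (ENSMUSG00000037486, mm10 chromosome 12, 3426857 to 3506852) stood at 109 ± 2.48 CPM with the empty vector (SD, n = 2). It stood at 1188 ± 277 CPM with full-length ASXL2 (SD, n = 2) and at 1201 ± 430 CPM in the pooled mutants (SD, n = 6). The 8 libraries with a construct averaged 10.98 times the empty vector level in CPM and 20.9 times in TPM. By label, mutant 1 averaged 1719 CPM, mutant 2 averaged 1031 CPM and mutant 3 averaged 853 CPM, each over 2 libraries. Construct libraries of batch 1 in the deposited names lay between 1132 and 1892 CPM, and those of batch 2 between 790 and 992 CPM. By these names both libraries labelled mutant 1 lie in batch 1 and both labelled mutant 3 in batch 2. The 3 means therefore cannot be told from the batch, which also enters the SD of the pooled mutants. The lowest library with a construct, at 790 CPM, lay above the highest empty vector library, at 111 CPM. Of the 2 over-expressed Asxl2 transcripts, the longer one, ENSMUST00000153102, spans the last coding exon. On average it made up 34.7% of their joint excess TPM over the empty vector with full-length ASXL2. In the mutants it made up 35.5 ± 1.10% (SD, n = 6), so this measure did not separate the constructs. TPM is scaled by length, and in estimated counts the longer one was the larger, at 65447 against 38376 in full-length replicate 1. The paralogue Asxl1 (105 CPM with the empty vector, 103 with full-length ASXL2 and 96.3 in the mutants) and Bap1 (78.04, 74.7 and 77.3 CPM) did not pass the test in any pooled comparison.

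**Figure D1:**
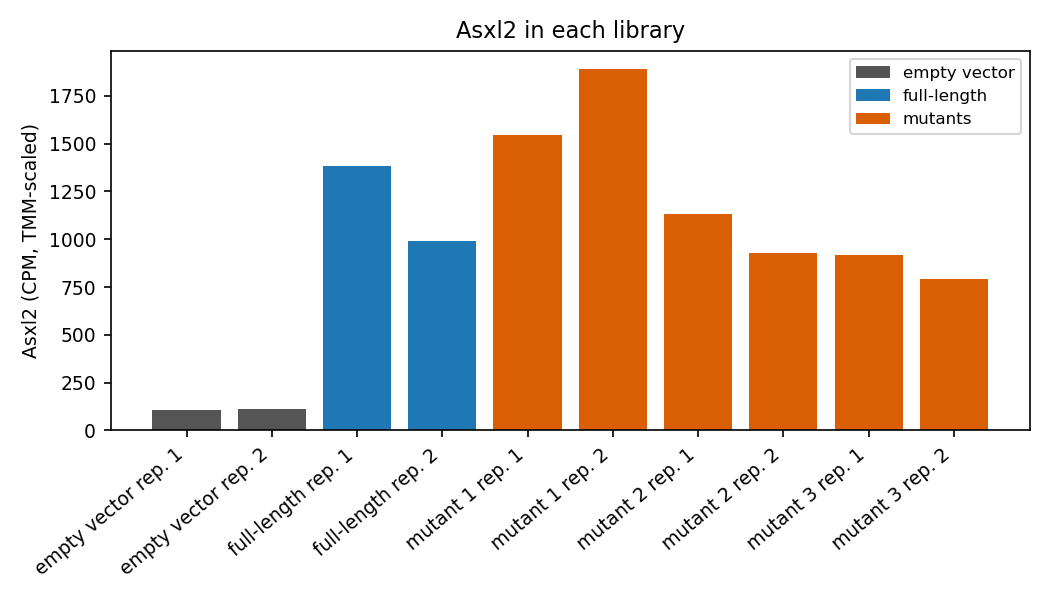
Asxl2 in CPM (vertical axis, from 0) in each of the 10 libraries, 1 bar per library, coloured by class. The bars with a construct start at 790 CPM, and those with the empty vector reach 111 CPM.

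The expanded cells of all groups carried transcripts of mast cells and basophils at high levels. Carboxypeptidase A3 (Cpa3), a mast cell granule protease, ranged from 19385 to 27096 TPM over the 10 libraries, and the chymase Cma1 from 9555 to 15983 TPM. The tryptase Tpsb2 ranged from 7782 to 12531 TPM, the IgE receptor chain Fcer1a from 5760 to 8224 TPM and the serotonin synthesis enzyme Tph1 from 3155 to 4994 TPM. Of the 27 members of the mast cell and basophil list, 22 averaged at least 10 TPM, and the list took between 6.59 and 7.95% of all TPM. TPM values are shares of a total, in which the highest gene, Mir6236, ranged from 38966 to 109219 TPM over the 10 libraries. That difference enters the TPM ranges given here. Members of other lineage lists varied. Under 1 TPM on average were 23 of 24 lymphoid, 21 of 23 neutrophil maturation, 16 of 19 stromal and endothelial, 9 of 11 eosinophil, 17 of 24 monocyte and macrophage, 13 of 19 dendritic cell, 9 of 15 neutrophil primary granule and 14 of 24 erythroid genes, but 8 of 20 megakaryocyte and 8 of 25 stem and progenitor genes. Of the last 2 lists, 9 and 12 members averaged at least 10 TPM. The mast cell and basophil list was not called in any pooled comparison by camera. Its median log2 fold change was 0.074 for full-length ASXL2 against the empty vector (adjusted p = 0.694), 0.034 for the mutants against the empty vector (adjusted p = 0.732) and 0.0098 for the mutants against full-length ASXL2 (adjusted p = 0.936).

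The largest part of the variance did not follow the constructs. The first principal component carried 41.2% of the variance and placed 5 libraries on each side. Of the 10 libraries, 8 lay on the side of their labelled batch, and the exceptions were mutant 1 replicate 2 and mutant 3 replicate 1. The deposited data of 4 mutant libraries carry another mutant number in their names than the label, and for these 2 libraries the batch differs as well. By the batch in those names, 10 of the 10 libraries lay on the side of their batch. Groups were taken from the labels throughout, so values for a single mutant carry this limit, and the pooled mutant class does not depend on the mutant number. The second component carried 16.0% of the variance and set the empty vector libraries, at -50.4 and -44.2, apart from the libraries with a construct, which lay between 1.28 and 21.8.

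**Figure D2:**
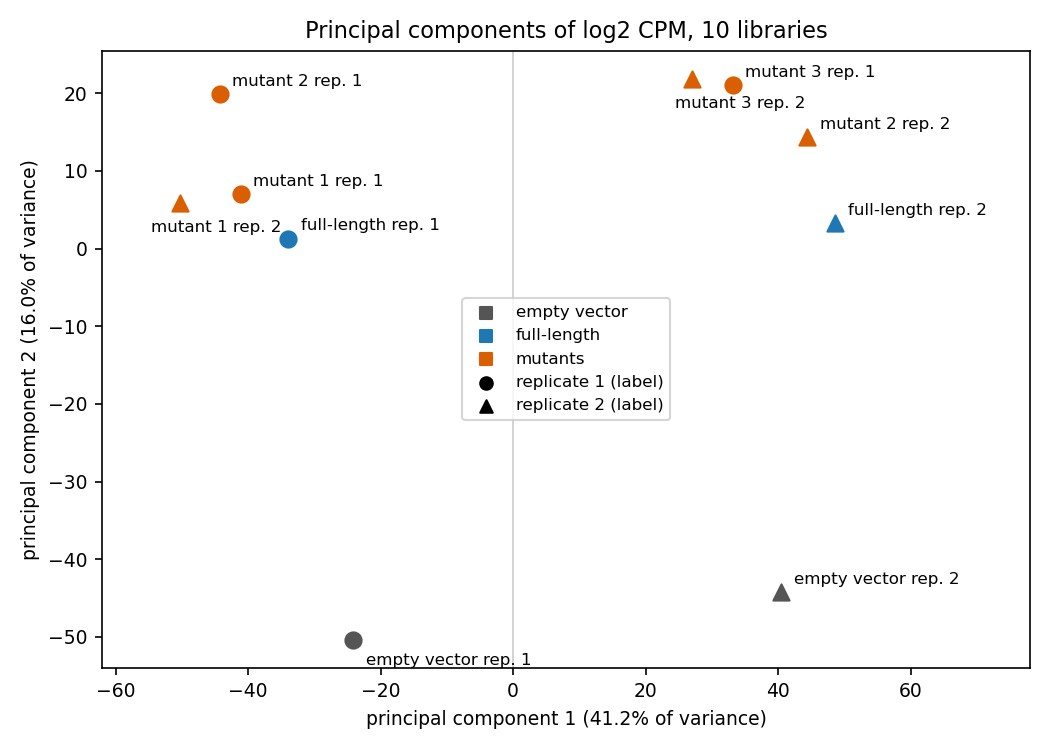
Scores of the 10 libraries on principal components 1 and 2 (41.2 and 16.0% of the variance), coloured by class, with the marker shape giving the labelled replicate. Mutant 1 replicate 2 and mutant 3 replicate 1 lie with the other replicate number on the horizontal axis, and the empty vector libraries lie lowest on the vertical axis.

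The comparison of full-length ASXL2 with the empty vector asks what differed in the libraries labelled full-length. Beside Asxl2, the genes with the largest rises have varied known roles. Rab11fip5, an effector of recycling endosomes, rose from 1.87 ± 0.910 to 20.1 ± 4.24 CPM (log2 fold change 3.42, SE 0.56, adjusted p = 0.0344; SD, n = 2 each). The lipid carrier Apoe rose by 2.81 on the log2 scale (SE 0.49, adjusted p = 0.0404), and its full-length libraries were uneven, at 45.9 ± 29.6 CPM. The sorting receptor Sort1 rose by 2.40, the adenylyl cyclase Adcy6 by 2.38 (SE 0.23, adjusted p = 0.00570), the focal adhesion gene Tns1 by 2.33 and the zinc finger factor Sall2 by 2.32. Cand2 rose by 2.22, Arhgef5 by 2.14 and the PI3-kinase catalytic subunit Pik3cb by 2.03.

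The falls with full-length ASXL2 were fewer and smaller. Gfi1 (mm10 chromosome 5, 107716657 to 107726036), a transcriptional repressor that acts in granulocyte development, went from 25.5 ± 1.90 to 6.77 ± 2.12 CPM. Its log2 fold change was -1.91 (SE 0.35, adjusted p = 0.0462). The sialomucin Podxl changed by -1.22, Rgs7bp by -1.14, the cytochrome Cyp1b1 by -1.07 and the Ras exchange factor Rasgrp1 by -1.01. The splicing regulator Hnrnpll changed by -0.79, the transcript AU020206 by -0.77, the nucleotide transporter Slc17a9 by -0.60 and the cytokine Il6 by -0.51. The ectonucleotidase Entpd1 (log2 fold change -1.40) passed only in the fit with the replicate block, with an adjusted p of 0.0371 there and 0.111 without it. With that block Podxl (adjusted p = 0.0517) and Slc17a9 (adjusted p = 0.0603) no longer passed. All 20 named genes, Asxl2 included, had the same sign in the mutants against the empty vector. Since both comparisons share the empty vector libraries, this says little: genes picked in the same way from simulated unchanged groups had the same sign for 97.7% on average over 20 simulations. Of the 20 genes, 18 passed in the mutants too. Without Entpd1 the share was 89.5%, against between 27.8 and 65% in the simulations, where as many genes with the smallest p were taken as were called.

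By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05, 122 genes were higher and 12 lower with full-length ASXL2 among 17810 tested. With the replicate block the counts were 115 and 14. With the batch of the deposited names as the replicate block they were 686 and 217, and the 134 unblocked calls were among them. Without empty vector replicate 1 the total was 4 and without replicate 2 it was 0 (1270 at an unadjusted p under 0.05), and without full-length replicate 1 or 2 it was 47 or 9. Leaving out replicate 1 or 2 of mutant 1 gave 53 or 74, of mutant 2 gave 57 or 86, and of mutant 3 gave 75 or 43. DESeq2 called 560 genes, while the fit of only the libraries compared and the fit of only libraries whose deposited name matches the label called 0 each by edgeR, with 921 and 1086 genes at an unadjusted p under 0.05. A test on log2(TPM + 1) called 9 higher and 5 lower, and the fit without the 2 mutant libraries that lie with the other batch, chosen after seeing the data, called 37.

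Among the lists fixed before the data were examined, camera with a preset correlation of 0.01 called 5 of the 26 tested for full-length ASXL2 against the empty vector. The ribosome biogenesis and MYC target list lay lower, with 28 of 30 members below the empty vector, a median log2 fold change of -0.27 and an adjusted p of 1.32e-05. No member passed by itself, and the nucleolar genes Npm1 and Nop56 stood at log2 fold changes of -0.32 and -0.35. With the batch of the deposited names as a block, 11 members fell, and no member of the other called lists passed. The ATF4 and unfolded protein response list (median -0.15, adjusted p = 0.0162) and the S phase list (median -0.12, adjusted p = 0.0281) also lay lower. The cholesterol biosynthesis list (median 0.15, adjusted p = 0.0281) and the glycolysis and hypoxia list (median 0.28, adjusted p = 0.0440) lay higher. With an estimated correlation none of these 5 calls held. The adjusted p was 0.829 for ribosome biogenesis and for ATF4 and 0.836 for the other lists. This correlation was estimated without a block, so joint differences of the members between the batches enter it. It was not estimated with a block. Within batch 1 and batch 2 of the deposited names, each with 1 full-length and 1 empty vector library, the medians were -0.38 and -0.17 for ribosome biogenesis, -0.20 and -0.13 for ATF4, and 0.15 and 0.15 for cholesterol. Glycolysis (0.41 and -0.031) and S phase (-0.34 and 0.061) differed in sign between the batches. With that batch as the replicate block the glycolysis list no longer passed (adjusted p = 0.0550), and the interferon response list did (adjusted p = 0.0190). The glycolysis list had a median of -0.27 without full-length replicate 1, and the cholesterol list had -0.089 there and -0.0105 without empty vector replicate 2. The S phase list had 0.024 without full-length replicate 1. Each of these fits leaves 1 class in 1 batch of the deposited names, so the difference between the batches enters it. The number of lists called was 0 without empty vector replicate 2 and 1 without full-length replicate 1.

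Single members of other lists also passed in this comparison. The erythropoietin receptor Epor rose by 1.45 (SE 0.21), the endothelial coreceptor Eng by 1.46 (SE 0.23), the class II chaperone H2-DMa by 0.69 (SE 0.13) and the Polycomb subunit Cbx2 by 0.66 (SE 0.12). With the replicate block H2-DMa (adjusted p = 0.0582) and Cbx2 (adjusted p = 0.0542) no longer passed, and the coagulation factor gene F13a1 did (log2 fold change 2.08, adjusted p = 0.0419). Without the block each of the 4 was the only tested member of its lineage or complex list past the threshold, of 19 erythroid, 8 stromal and endothelial, 13 dendritic and 30 Polycomb genes. Of the 27 mast cell and basophil genes, Il6 fell and 26 did not pass. Adjusted over the list alone, 5 rose and 1 fell of the 23 inflammatory cytokine genes, against 0 and 1 over all genes, and 2 rose of the 16 monocyte and macrophage genes, against 0.

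The comparison of the pooled mutants with the empty vector asks the same question of the mutant proteins. The lysosomal protease Ctsl rose from 0.862 ± 0.101 CPM (SD, n = 2) to 13.1 ± 6.06 CPM (SD, n = 6), with a log2 fold change of 3.91 (SE 0.57, adjusted p = 0.0122). The procollagen protease Bmp1 rose by 3.45, the adhesion adaptor Bcar1 by 3.28 and the ubiquitin-conjugating enzyme Ube2e2 by 3.24. Trp53i11 rose by 3.20, Adcy6 by 2.80 (SE 0.21, adjusted p = 0.000860), Rasgef1a by 2.77, Sel1l3 by 2.65 and the actin crosslinker Actn1 by 2.63. Among the falls, Plac8 went from 6.69 to 1.07 CPM (log2 fold change -2.65, SE 0.56, adjusted p = 0.0492, and 0.0672 with the replicate block), and Entpd1 from 53.9 to 17.0 CPM (-1.66, SE 0.25). Gfi1 changed by -1.59 (SE 0.26, adjusted p = 0.0190), the glutamate receptor Grm6 by -1.56, the OX40 ligand Tnfsf4 by -1.30 and AU020206 by -1.15 (SE 0.10, adjusted p = 0.00111). Nlrc3 changed by -1.11, Tram2 by -1.04, Podxl by -1.03 and the Ras GTPase activator Rasa2 by -0.86. All 20 named genes, Asxl2 included, had the same sign with full-length ASXL2, where simulated unchanged groups gave 96.5% on average. With full-length ASXL2 6 of them (30%) passed, within the 5 to 45% of the simulations.

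**Figure D3:**
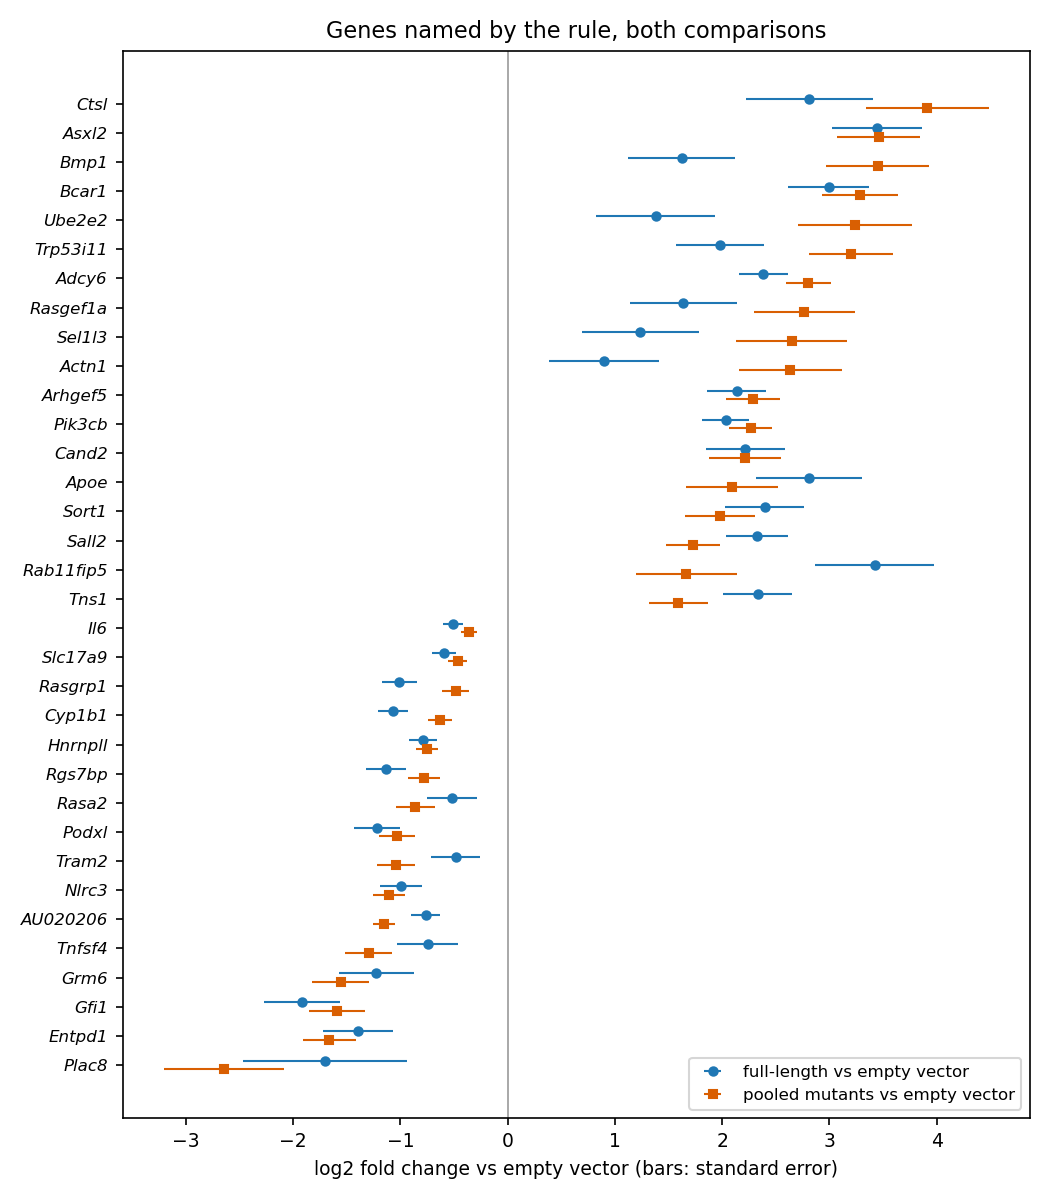
Log2 fold change against the empty vector (horizontal axis, with its standard error) for the named genes of both comparisons, full-length ASXL2 as circles and pooled mutants as squares. All genes shown lie on the same side of 0 in both comparisons, and Ctsl reaches 3.91 and Plac8 -2.65 in the mutants.

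In this comparison 262 genes were higher and 49 lower by edgeR's quasi-likelihood test. The replicate block gave 288 and 47, and the batch of the deposited names as the replicate block gave 1214 and 711, with the 311 unblocked calls among them. Without empty vector replicate 1 the total was 28, and without replicate 2 it was 17. Without mutant 1 replicate 1, mutant 2 replicate 1 and mutant 3 replicate 2, each left out alone, it was 207, 186 and 183. DESeq2 called 913 genes, the fit of only the libraries compared 279 and the fit of only libraries whose deposited name matches the label 0 by edgeR, with 1155 at an unadjusted p under 0.05. On log2(TPM + 1) 46 were higher and 23 lower. Without the 2 mutant libraries that lie with the other batch, an alternative chosen after seeing the data, the total was 162.

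Of the 26 lists tested in the mutants against the empty vector, 6 were called. The glycolysis and hypoxia list lay higher, with 25 of 27 members above the empty vector, a median log2 fold change of 0.63 and an adjusted p of 6.3e-12. The glucose transporter Slc2a1 rose by 0.63 (SE 0.12, adjusted p = 0.0277). The phosphofructokinase Pfkp (0.67), the pyruvate dehydrogenase kinase Pdk1 (1.61) and the hexokinase Hk2 (0.87) did not pass over all genes, and 6 members rose when adjusted over the list alone. With the replicate block Pfkp (adjusted p = 0.0262) and Pdk1 (adjusted p = 0.0159) passed, and with the batch of the deposited names as the block 6 members rose. The list was higher within both batches of the deposited names, with a median of 0.54 in batch 1 and 0.68 in batch 2. With an estimated correlation, again without a block, its adjusted p was 0.660.

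The other 5 lists called in the mutants lay lower. These were ribosome biogenesis and MYC targets (median -0.26, 29 of 30 members below, adjusted p = 1.60e-07), S phase (-0.21, 33 of 35, adjusted p = 1.65e-05) and mitosis (-0.16, 29 of 30, adjusted p = 0.00492). The other lists were ATF4 and unfolded protein response (-0.19, 25 of 28, adjusted p = 0.000270) and p53 targets (-0.23, 18 of 24, adjusted p = 0.000376). The p53 target Eda2r fell by 0.69 (SE 0.13), while Ccng1, Tnfrsf10b and Mdm2 stood at -0.36, -0.47 and -0.16 without passing. With the batch of the deposited names as the replicate block, 21 of the 30 ribosome biogenesis, 11 of the 28 ATF4 and 9 of the 24 p53 target genes fell, 2 p53 target genes rose, and no S phase or mitosis gene passed. Among lists that were not called, that block had 7 Polycomb genes higher and 1 lower, and 5 heat shock genes lower and 1 higher. With a correlation estimated without a block none of the 5 held. The adjusted p was 0.248 for p53 targets, 0.700 for mitosis and 0.691 for the other lists. Within the batches of the deposited names the mitosis list went both ways, at -0.51 in batch 1 and 0.13 in batch 2, and the S phase list stood at -0.45 and -0.0039. The p53 target list stood at -0.23 and -0.19, the ribosome biogenesis list at -0.41 and -0.18 and the ATF4 list at -0.32 and -0.071. Members that passed in lists that were not called were Procr, Il1b, Ccl3, Epor, Pcgf5, Cbx2, Apoe, Il6st and, in the BAP1 complex list, Asxl2 itself, which rose, and Gfi1, Il6 and Spry1, which fell. With the replicate block Cx3cr1 (adjusted p = 0.0403), Eng (adjusted p = 0.0399) and Cbx6 (adjusted p = 0.0491) passed too. Fry, which asks whether the members of a list move 1 way on balance, called the BAP1 complex and interferon lists for full-length ASXL2 (adjusted p = 0.0203 each) and the Polycomb, BAP1 complex and p53 target lists for the mutants (adjusted p = 0.0405 each). The over-expressed Asxl2 is a member of the BAP1 complex list and the only 1 of its 11 tested members that passed against the empty vector, so that these calls of fry are no evidence of a change in the rest of the list.

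The other 20 tested lists were not called in the mutants against the empty vector, with adjusted p between 0.0538 and 0.881. The replicate block by label gave 8 called lists in all, 3 higher and 5 lower, against 1 higher and 5 lower without it. With full-length ASXL2 the lists that were not called had adjusted p between 0.0917 and 0.975. Among blood lineage lists, the median log2 fold changes of full-length ASXL2 and of the mutants were -0.0050 and 0.099 for stem and progenitor genes, -0.19 and 0.095 for neutrophil primary granule genes, and 0.51 and 0.20 for neutrophil maturation genes. They were 0.055 and -0.043 for monocyte and macrophage genes, -0.019 and 0.11 for erythroid genes, -0.021 and 0.074 for megakaryocyte genes, 0.39 and 0.57 for lymphoid genes, 0.11 and 0.16 for dendritic cell and MHC class II genes, and -0.22 and -0.19 for stromal and endothelial genes. Polycomb genes stood at 0.024 and 0.020, BAP1 complex genes at -0.012 and 0.0065, interferon response genes at 0.18 and 0.13, NF-kB and inflammatory cytokine genes at 0.12 and 0.059 and immediate early genes at 0.066 and 0.032. PPAR and LXR targets stood at 0.098 and 0.19, heat shock genes at -0.042 and -0.12, haematopoietic transcription factors at 0.0099 and 0.080, and cytokine receptors and signalling feedback genes at 0.034 and 0.067. The cholesterol list stood at 0.10 in the mutants, and the mitosis and p53 target lists at -0.068 and -0.055 with full-length ASXL2. In the mutants, the test pointed against the median for the neutrophil primary granule, megakaryocyte, stromal and immediate early lists, and the mean of the heat shock list was 0.014. With full-length ASXL2 it did so for the monocyte, erythroid, megakaryocyte, stromal, BAP1 complex and immediate early lists. The eosinophil and Hoxa lists had 4 and 2 members tested, too few for a test, and none of the 13 mitochondrially encoded genes was matched.

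The comparison of the mutants with full-length ASXL2 is the one the design names. No gene passed by edgeR's quasi-likelihood test, with 720 genes at an unadjusted p under 0.05. DESeq2 called 76 genes and the test on log2(TPM + 1) called 0. Galnt12 (mm10 chromosome 4, 47091909 to 47123070), an enzyme that starts mucin-type O-glycosylation, passed in the fit with the replicate block by label, with an adjusted p of 0.0265 there. With the batch of the deposited names as the block Galnt12 passed as well (adjusted p = 0.00816). It stood at 3.22 ± 0.653 CPM with full-length ASXL2 and 10.5 ± 1.75 CPM in the mutants (log2 fold change 1.70, SE 0.21), and at 2.63 ± 0.250 CPM with the empty vector. Asxl2 itself differed by 0.016 (SE 0.31). In simulated data with these class sizes and depths, 17447 genes were tested. A 4-fold change between these classes was called for 69.7% of genes, a 2-fold change for 47.8% and a 1.5-fold change for 14.9%. The simulated counts held no batch and took their spread from the fit without a block, so these shares need not hold for the real libraries.

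With the batch of the deposited names as the replicate block, 33 genes were higher and 38 lower in the mutants than with full-length ASXL2. The genes named here were taken from that fit after its values were seen, by the same rule. Among the higher ones were Ube2e2 (log2 fold change 1.86 without the block), Galnt12 (1.70), Auts2 (1.68) and Emp2 (1.44). The collagen gene Col27a1 (1.37), Cobll1 (1.24) and Trp53i11 (1.22) were higher too. Among the lower ones were Sec14l2 (-1.97), Dnah2 (-1.50), Soga1 (-1.46), the B cell scaffold Bank1 (-1.20) and the aspartic protease Napsa (-0.92). The leukocyte integrin chains Itgb2 (-1.08) and Itgal (-0.89) were lower too. Itgb2 stood at 17.6 ± 3.54 CPM with the empty vector, 55.3 ± 3.02 with full-length ASXL2 and 26.1 ± 5.002 in the mutants.

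Camera called 7 lists between the mutants and full-length ASXL2. Glycolysis and hypoxia (median 0.34, 26 of 27 members above, adjusted p = 2.36e-11) and stem and progenitor genes (0.12, 17 of 21, adjusted p = 0.0315) lay higher. The lists that lay lower were p53 targets (-0.12, 20 of 24, adjusted p = 0.00231), mitosis (-0.086, 30 of 30, adjusted p = 0.0315), S phase (-0.079, 31 of 35, adjusted p = 0.0388), interferon response (-0.041, 19 of 29, adjusted p = 0.0388) and monocyte and macrophage genes (-0.13, 10 of 16, adjusted p = 0.0388). No member of these lists passed over all genes, and with the batch of the deposited names as the replicate block 2 interferon response genes fell. With an estimated correlation none of the 7 held. The adjusted p was 0.463 for glycolysis and 0.190 for stem and progenitor, p53 and interferon genes. It was 0.296 for monocyte genes and 0.962 for the cell cycle lists. The correlation was estimated without a block, so joint differences of the members between the batches enter it. The full-length libraries differed from each other in the glycolysis list, at 0.72 and -0.25 relative to the empty vector mean, while the 6 mutant libraries lay between 0.25 and 0.79. Within batch 1 of the deposited names the mutants exceeded full-length ASXL2 by a median of 0.047, and within batch 2 by 0.79. In those batches stem and progenitor genes stood at 0.061 and 0.18, p53 targets at -0.071 and -0.17, mitosis at -0.16 and -0.065, S phase at -0.11 and -0.059, and interferon response at -0.035 and -0.14. Monocyte genes differed in sign, at 0.058 and -0.46, and with that batch as the replicate block their list no longer passed (adjusted p = 0.0878), which left 6 lists called. Without full-length replicate 2 the glycolysis list stood at -0.022, mitosis at 0.21 (adjusted p = 0.0338), S phase at 0.098 and monocyte genes at 0.30, and 3 lists were called. The number called was 2 without empty vector replicate 1, empty vector replicate 2 or mutant 1 replicate 2, 3 without mutant 1 replicate 1 and 4 without mutant 3 replicate 2. It was also 2 without the pair of mutant libraries that lie with the other batch. The fit without full-length replicate 2 sets a full-length library of batch 1 alone against mutants of both batches, so the difference between the batches enters it. Within batch 1 glycolysis, mitosis and S phase kept the sign they had with all libraries, and monocyte genes did not.

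**Figure D4:**
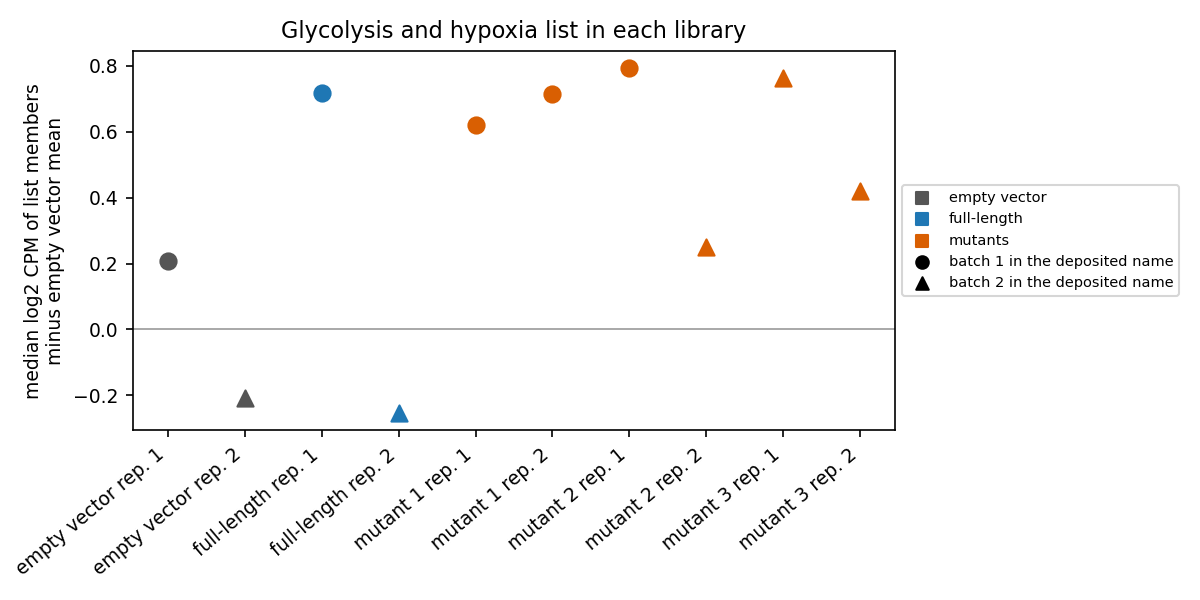
Median log2 CPM of the 27 glycolysis and hypoxia genes in each library, minus the empty vector mean (vertical axis), coloured by class, with the marker shape giving the batch of the deposited name. The full-length libraries lie at 0.72 and -0.25 and the 6 mutant libraries between 0.25 and 0.79.

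The fold changes of full-length ASXL2 and of the mutants share the empty vector libraries as control. Across the 17810 genes, which are not independent replicates, their Pearson correlation was 0.728, against a mean of 0.627 in 20 simulations of unchanged groups with the same controls. Their covariance was 0.261 against 0.152 in the simulations. The sign was the same for 78.1% of genes, against 71.2% in the simulations. Both comparisons called 106 genes, 97 higher and 9 lower, and 0 genes were called in opposite directions. In the simulations, where as many genes with the smallest p were taken in each direction as were called, between 52 and 65 were shared (mean 58.2), so that much of such an overlap can come from the shared controls alone. The empty vector has too few libraries to be split into parts of 2 each. The correlation did not exceed the simulations in each subset of the libraries. Without full-length replicate 1 it was 0.390, within the 0.389 to 0.484 of simulations that lack the same library. Without empty vector replicate 2 it was 0.800, within 0.789 to 0.829. The simulations hold no batch, and leaving out such a library leaves its class in 1 batch of the deposited names. For these subsets the simulated range therefore cannot decide whether the excess is present. Without full-length replicate 2 (0.585) and without empty vector replicate 1 (0.830) the correlation lay above such simulations, which reached 0.495 and 0.816, with the same limit. Without single mutant libraries it lay between 0.710 and 0.733, against at most 0.644.

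Taken by label, mutant 1 gave 38 higher and 3 lower genes against the empty vector, mutant 2 gave 50 and 2, and mutant 3 gave 80 and 4, by edgeR's quasi-likelihood test in a fit with 5 groups. By the deposited names both libraries labelled mutant 1 lie in batch 1 and both labelled mutant 3 in batch 2. The empty vector and full-length ASXL2 have 1 library in each. Without a block, the tests of mutants 1 and 3 are therefore not balanced over this batch. In the test among the mutants without a block, a difference between mutants 1 and 3 cannot be told from the batch. A fit with this batch as the block takes the batch difference from the groups with 1 library in each. The genes with the smallest p included Asxl2, Adcy6, Tpd52 and Gm26880 for each mutant. Tpd52 rose by 1.72, 1.77 and 1.74, and the transcript Gm26880 changed by -2.04, -2.53 and -2.53 in mutants 1, 2 and 3. Arhgef5 for mutant 1 (2.48) and Anks6 for mutants 2 and 3 (3.23 and 3.34) completed these lists. Against full-length ASXL2 no gene passed for any single mutant, with 740, 526 and 812 genes at an unadjusted p under 0.05, while DESeq2 called 45, 30 and 93. The test among the 3 mutants called 0 genes, with 757 at an unadjusted p under 0.05 and 33 by DESeq2. It also called 0 with the batch of the deposited names as the replicate block, with 779 at an unadjusted p under 0.05. With that block mutant 1 differed from full-length ASXL2 in 0 genes, mutant 2 in 6 and mutant 3 in 99. Mutants 1 and 3 each lie in 1 batch and their labels are in question, so these counts do not rank the mutants. Against the empty vector that block gave 392, 751 and 1032 genes for mutants 1, 2 and 3. The replicate block by label raised the count of mutant 3 against the empty vector from 84 to 132.

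These counts for single mutants moved with single libraries. For mutant 1 against the empty vector the total was 1 without empty vector replicate 1 or either library of mutant 1, 2 without empty vector replicate 2, 4 without either library of mutant 3, and 103 or 142 without mutant 2 replicate 1 or 2. For mutant 2 it was 3 without either empty vector library, 16 or 10 without mutant 1 replicate 1 or 2, 6 or 101 without mutant 2 replicate 1 or 2, and 5 or 15 without mutant 3 replicate 1 or 2. For mutant 3 it was 1 or 2 without empty vector replicate 1 or 2, 23 or 25 without mutant 1 replicate 1 or 2, and 5 or 2 without mutant 3 replicate 1 or 2.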

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

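All tests in this part were chosen after the results they measure were seen, except the list differences between mutants and full-length ASXL2, which were planned.

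The first principal component placed mutant 1 replicate 2 and mutant 3 replicate 1 with libraries of the other replicate number. Depth was tested as an explanation, and the best limit on the total count misplaced 2 of the 10 libraries. The construct as labelled was tested as well, and 2 of the 5 labelled groups had both libraries on 1 side. The batch in the deposited names placed 10 of 10 libraries on its side, so a candidate explanation is that the label and the data of these libraries were paired differently at deposit. Which of the pair is right stays open, and the biological origin of the split was not tested.

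Transcript values, which the gene comparisons do not use, stood out above the empty vector at Asxl2. ENSMUST00000144247 (mm10 chromosome 12, 3426884 to 3496284, 12 exons, 1211 coding nucleotides) averaged 390 TPM in the 8 libraries with a construct against 9.14 TPM with the empty vector. ENSMUST00000153102 (3426901 to 3502466, 12 exons, 4110 coding nucleotides) averaged 212 TPM against 6.998 TPM.

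The longer of these 2 transcripts, ENSMUST00000153102, spans the last coding exon of Asxl2. With full-length ASXL2 it averaged 34.7% of their joint excess TPM over the empty vector. In the mutants it averaged 35.5 ± 1.10% (SD, n = 6). The 2-sided exact permutation test of full-length against mutants gave p = 0.5 over 28 splits, where 0.0357 is the smallest possible. An assignment of reads that gives every library 1 share was tested on the same 2 transcripts, without subtracting the empty vector. The long one, ENSMUST00000153102, took 40.002 and 46.7% with the empty vector (mean 43.3%) and between 34.3 and 37.2% with a construct. The means differed by 7.81 points, where the 8 construct libraries had an SD of 1.08, and both empty vector libraries lay above all 8 (exact permutation p = 0.0222 over 45 splits). This argues against 1 share for every library, but not against 1 share for all libraries that over-express Asxl2. A construct of the same extent in the libraries labelled full-length and mutant may account for the likeness of the shares. Mutants with small changes in an otherwise full coding sequence may do so too. Neither accounts for the level of 34.7%. In the full-length libraries the short transcript, ENSMUST00000144247, stood at 458 and 322 TPM and the long one at 239 and 179 TPM. In estimated counts, which are not scaled by length, the short one stood at 38376 and 21782 and the long one at 65447 and 39572. The construct sequences were not used here, so the extent stays open, and no biological explanation was tested.

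The glycolysis and hypoxia list differed between mutants and full-length ASXL2 by a median of 0.34 on the log2 scale by camera's test with a preset correlation. It was not called with an estimated correlation (adjusted p = 0.463) or by fry (adjusted p = 0.764), both run without a block. An uneven spread of the classes over the batches is argued against by the design, since batch 1 of the deposited names holds 50% of the mutant and 50% of the full-length libraries. Without full-length replicate 2 the median was -0.022, so 1 full-length library may decide the difference. That fit sets full-length ASXL2 of batch 1 alone against mutants of both batches. Within batch 1 the median was 0.047 and within batch 2 it was 0.79. A biological difference between mutant and full-length ASXL2 stays open, since 2 full-length libraries cannot tell it from a difference between these libraries.

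Of the other lists that differed between mutants and full-length ASXL2 by camera's test, stem and progenitor genes had a median of 0.12, monocyte and macrophage genes -0.13 and p53 targets -0.12. S phase genes had -0.079, mitosis genes -0.086 and interferon response genes -0.041. With an estimated correlation none of these 6 was called, with adjusted p between 0.190 and 0.962, and fry called none. Both were run without a block. Without full-length replicate 2 the medians of mitosis (0.21), S phase (0.098) and monocyte genes (0.30) had the opposite sign. That fit sets full-length ASXL2 of batch 1 of the deposited names alone against mutants of both batches. Within batch 1 and batch 2 mitosis stood at -0.16 and -0.065 and S phase at -0.11 and -0.059, so neither reversed there. Monocyte genes stood at 0.058 and -0.46.

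Among the 6 mutant libraries, 16 of 219 genes had 1 library far from the rest, with a gap over 0.625 of the range, where chance flags about 1 in 20 groups, or 10.95 genes here. In mutant 1 replicate 1, Itgam stood at 1.87 CPM (others at most 0.838), Prtn3 at 2.55 (at most 0.384), Cd74 at 1.59 (at most 0.929), Csf2rb2 at 11186 (at most 10301) and Atf3 at 0.208 (at least 0.346). In mutant 1 replicate 2, Gp9 stood at 2.14 CPM (at most 1.27), in mutant 2 replicate 1 Klf1 at 1.26 (at most 1.13) and in mutant 2 replicate 2 Tram2 at 8.46 (at most 6.40). In mutant 3 replicate 1, Srebf2 stood at 377 CPM (at most 328), Il3ra at 99.3 (at most 77.6), Dusp1 at 8.35 (at most 4.93) and Osm at 219 (at most 152). There Chordc1 stood at 47.4 (at least 52.6) and Ms4a3 at 2.93 (at least 3.73). In mutant 3 replicate 2, Hoxa7 stood at 5.21 CPM (at most 0.0445) and Hoxa9 at 9.23 (at most 0.0393).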

How the results depend on the processing

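The alternatives without the pair of mutant libraries on the other side of the first component, and with the replicate block on libraries whose deposited name matches the label, were chosen after the data were seen. The cause of each change was not tested, but the design settles some points. Fits with fewer libraries have fewer residual degrees of freedom. The batch of the deposited names holds 50% of each pooled class, so without a block its differences count as residual spread. Fitted as the block, it takes them out, and no unblocked gene call of the pooled comparisons was lost. Where a library left out leaves a group with 1, that library is assumed to vary like the other groups.

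Asxl2 rose 20.9 times in TPM. Genes called for full-length ASXL2 against the empty vector, 134, became 57 with 5 groups, 446 with name-matched libraries and the replicate block, 560 with DESeq2, 86 with length offsets, 14 with limma on log2(TPM + 1), 0 with name-matched libraries only, 0 with only the libraries compared, 903 with the deposited-name replicate block and 37 without the pair. For the pooled mutants against the empty vector, 311 became 194, 567 and 913 in the first 3 of these settings, 69 with limma, 0 with name-matched libraries only, 201 with the fold threshold, 1925 with the deposited-name replicate block and 162 without the pair. For the pooled mutants against full-length ASXL2, 0 became 76 with DESeq2, 71 with the deposited-name replicate block, 1 with the replicate block and 7 with name-matched libraries and the replicate block.

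For mutants 1, 2 and 3 against the empty vector, DESeq2 called 534, 503 and 629 genes, limma 4, 3 and 13, no filter 166, 194 and 280, and the deposited-name replicate block 392, 751 and 1032. Length offsets gave 27 for mutant 1 and 53 for mutant 3, and name-matched libraries gave 0 for both. The replicate block gave 132 for mutant 3. Against full-length ASXL2, DESeq2 called 45, 30 and 93, no filter 3, 2 and 14, limma 1 for mutant 3, and the deposited-name replicate block 0, 6 and 99. Among the 3 mutants DESeq2 called 33, limma 1 and no filter 2. No value could be had for mutant 2 or among the mutants with name-matched libraries only, or among the mutants with the fold threshold.

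The lists called, 5, 6 and 7, became 0, 0 and 0 with an estimated correlation and 2, 3 and 0 with fry, both run without a block. For mutants against full-length ASXL2 they became 2 with name-matched libraries, with or without the replicate block, and 2 without the pair. Without full-length replicate 1 the medians against the empty vector reversed to -0.089 for cholesterol, -0.27 for glycolysis and 0.024 for S phase, and cholesterol stood at -0.0105 without empty vector replicate 2. The other ends of their ranges were 0.33 without empty vector replicate 1, and 0.65 and -0.32 without full-length replicate 2. Without full-length replicate 2 the medians of mutants against full-length ASXL2 reversed to -0.022 for glycolysis, 0.21 for mitosis, 0.30 for monocyte genes and 0.098 for S phase. Without full-length replicate 1 they were 0.91, -0.35, -0.34 and -0.23. Each of these fits leaves 1 class in 1 batch of the deposited names, so the difference between the batches enters it. Within batch 1 and batch 2 the mutants against full-length ASXL2 stood at 0.047 and 0.79 for glycolysis and -0.16 and -0.065 for mitosis. S phase stood at -0.11 and -0.059 and monocyte genes at 0.058 and -0.46. For full-length ASXL2 against the empty vector cholesterol stood at 0.15 and 0.15, glycolysis at 0.41 and -0.031 and S phase at -0.34 and 0.061.

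With each library left out in turn, the genes called ranged from 0 to 86 for full-length ASXL2 against the empty vector, 17 to 271 for the mutants against the empty vector and 0 to 1 for the mutants against full-length ASXL2. They ranged from 1 to 142, 3 to 101 and 1 to 100 for mutants 1, 2 and 3 against the empty vector, 0 to 1 for each against full-length ASXL2 and 0 to 0 among the mutants. The lists called ranged from 0 to 7, 4 to 8 and 2 to 8, and the correlation of fold changes from 0.390 to 0.830. Of the named genes and lists, 69 lost their call without empty vector replicate 1 and 75 without replicate 2, 2 lists (glycolysis for full-length ASXL2 against the empty vector, monocyte genes for the mutants against full-length ASXL2) did with the deposited-name replicate block, and 5 genes did with the replicate block by label, which changed no other call of a gene or list that passed without it.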

Other observations

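The rule behind the single-library genes and its use were chosen after the values were seen, and no hypothesis was tested on them.

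Some protein-coding genes were far higher in 1 library than in each of the other 9. With a minimum of 2 CPM (not TMM-scaled) and at least 10 times the next library, 11 genes in 5 libraries met the rule. In mutant 1 replicate 1 these were the eosinophil granule genes Epx (4.24 CPM, next library 0.0127) and Prg2 (4.71, next 0.115), the platelet chemokine Ppbp (4.84, next 0.232) and the aldehyde dehydrogenase Aldh1a1 (3.45, next 0.0516). In empty vector replicate 2 it was the T cell and stem cell surface gene Thy1 (18.5 CPM, next 0.0728). In mutant 1 replicate 2 they were Cd248 and Alpk3, and in full-length replicate 2 Rnase10 and Lrrc27 (30.3 CPM, next 1.59).

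Hoxa7 (mm10 chromosome 6, 52214491 to 52221854) stood at 5.19 CPM in mutant 3 replicate 2, next to 0.335 in full-length replicate 2. Its neighbour Hoxa9 (52223100 to 52231089), a homeobox gene of stem and progenitor cells, stood at 9.19 CPM in the same library. Hoxa9 stood at 1.11 CPM in empty vector replicate 1 and at most at 0.291 in the remaining libraries. The X-linked 8030474K03Rik also met the rule there, at 3.38 CPM.

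The labels give all groups the same culture with IL3, IL6 and SCF, and the transcripts of the IL3 receptor chain Csf2rb2 were among the 30 highest of all genes, at 3006 TPM on average and between 2417 and 3498 TPM over the 10 libraries. The serglycin gene Srgn, which encodes the core of granule proteoglycans, averaged 4741 TPM, and the granzyme gene Gzmb 3721 TPM.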
